A study of Mus musculus with 365 samples.

How the data were processed

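Single progenitor cells were sorted from femoral bone marrow of C57BL/6 mice that carry a transgene for Flt3 ligand (Flt3Ltg), a growth factor that expands early lymphoid and dendritic progenitors. Per the labels' protocols, cells were captured on Fluidigm C1 chips, cDNA was amplified over its full length by template switching with a SMARTer kit, and libraries were made with Nextera XT. Such libraries carry no molecular identifiers and do not mark the strand, so reads of a gene and of an antisense partner cannot be told apart. The sorted population is known as EPLM, early progenitors with lymphoid and myeloid potential, and the labels divide it into a Ly6D+ and a TN (triple negative) part. Each label names a pool of 2 mice and 1 of 6 capture chips.

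The deposited table holds raw read counts per gene and cell, which the authors left unnormalised, and a column of gene lengths that was not used here. Per the submitters' processing notes, the genome build was mm9 and R 3.2.0 was used. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here. Per the series' design text, 178 Ly6D+ and 232 TN cells were captured, and cells with fewer than 60% of reads mapped, too few counts or fewer than 800 detected genes were left out. The 152 Ly6D+ and 213 TN cells of the table are those that remained, and no further cell was left out of the main results. How doublets were treated is not given in the sources used here, and no doublet caller was run.

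The table names 23427 genes by Entrez identifier. Symbols were taken by identifier from a RefSeq gene table of assembly GRCm38.p6 for 23334 of them, and 93 kept their number. Because that assembly is not the build of the counts, it was used for names only and no coordinates are given. A row without a symbol, Entrez100861531, took 0.802% of all reads and up to 22.3% of the reads of a cell. At least 1 read was found for 14814 genes. Hbb-b2 and Hbb-bt hold the same counts, and genes with near-identical copies are uncertain in this way.

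The replicate was the chip, with 3 chips per population (TN chips 1, 2 and 3, Ly6D+ chips 4, 5 and 6). The labels do not say which mice went on which chip, so p-values measure the spread between chips, which may be technical. Each chip held cells of 1 population only, so chip effects and population cannot be separated by a model. Read counts were summed over the cells of each chip and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM normalisation, filterByExpr, Benjamini-Hochberg adjusted p under 0.05). Fold changes are Ly6D+ over TN, and standard errors are the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes.

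Gene lists (23) were fixed before the data were examined, as were the tests, most of the other settings and the rule for naming genes. Lists with 5 or more tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, beside an estimated correlation and fry. Named genes were up to 12 in each direction with an absolute log2 fold change of at least 1, no overlap of chip values and detection in 20% or more of the cells of the higher population, up to 3 members per list past the threshold, and genes fixed in advance (among them Ly6d, Siglech, Itgax, Ptprc, Kit, Klrb1c, Ebf1, Pax5, Rag1, Il7r, Dntt, Flt3, Csf1r, Mpo and Irf8). Klrb1c had reads in 7 cells and was too low to test. Some genes that the rule names are not reported here.

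For values per cell, each cell was thinned to 200000 gene reads. The lowest cell held 267852 reads, so no cell was lost. A gene was called detected at 5 or more thinned reads, which equals 25 CPM. Genes and list members detected per cell and the Spearman correlation between cells were averaged per chip, and the 6 chip values were compared by an exact two-sided permutation test, whose smallest p in this design is 0.1. Cells were grouped by Leiden clustering (scanpy 1.11.5, leidenalg 0.10.2) on 15 principal components of log2(CPM+1) of the 1500 most variable genes, with 15 neighbours and resolution 1. A cluster was called X-like from markers fixed in advance when 3 or more were detected in at least 20% of its cells, above the other cells, and a marker of that class stood among its top 10 genes; this scoring was set after the clusters were seen. Variable genes came from modelGeneVar (scran 1.30.0) with chip as a block. Relations within a population are Spearman correlations within each chip, given as mean ± SD of 3 chips, with no p-value over cells. Genes listed with an anchor gene were the extremes among those with the same sign on all 3 chips. The shared sign was thus part of the choice and is no replication.

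The steps were tested on simulated data. In 5 simulations of the Ly6D+ and TN chip sums over 11797 genes, edgeR recovered 5% of genes changed 2-fold and 45% of genes changed 4-fold, with 3.89% false calls, and camera called 4.8% of unchanged lists at an unadjusted p under 0.05. The simulated genes were drawn independently of each other. The camera rate therefore does not cover lists whose members vary together, such as interferon-response genes (estimated correlation 0.83). Alternatives were DESeq2 1.42.0, library size alone, no filter, a filter on detection in 10% of cells, thinned cells, limma-trend on chip means of log2(CPM+1), robust dispersion, each chip left out in turn, other detection limits, no thinning, other similarity measures, other clustering resolutions and other pseudocounts. Intervals and limits for counts of 0 (3 counts, over the number of cells) cover counting error only. Cells of a chip are not independent replicates, and amplified reads are not independent molecules. No pair of cells correlated above 0.644 (Pearson, log2 values), and no 2 columns were identical.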

Results

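Transcriptomes of 365 single bone marrow progenitor cells were measured in 2 sorted parts of the EPLM compartment, with 213 cells from the TN part and 152 cells from the Ly6D+ part. Ly6D is a surface protein used to mark lymphoid progenitors with B cell potential. The TN cells came from chips of 75, 69 and 69 cells and the Ly6D+ cells from chips of 40, 60 and 52 cells. The chips held between 35734620 and 61415823 gene reads in total. The median depth per cell was 823684, 808034 and 750934 reads on the TN chips and 923865, 1000070 and 894864 reads on the Ly6D+ chips. The design asks how the 2 populations differ in gene expression and how uniform the cells of each are.

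Ly6D+ cells held more transcript of lymphoid and B-lineage genes, and TN cells more transcript of myeloid and conventional dendritic genes, by camera with a preset correlation between genes. With an estimated correlation none of these 4 lists passed (adjusted p from 0.0535 to 0.125), and 3 of 15 early lymphoid, 3 of 21 B-lineage, 2 of 20 myeloid and 1 of 10 conventional dendritic members were called in these directions. The estimate was 0.10 for B-lineage and 0.13 for myeloid genes. For early lymphoid (−0.019) and conventional dendritic genes (−0.014) it lay below the preset 0.01, so a higher correlation does not account for their lost calls. The estimated setting therefore changes more than the correlation. How far correlation accounts for the lost B-lineage and myeloid calls was not tested. Ly6d itself was 15.9-fold higher in Ly6D+ (2823 ± 243 CPM, SD, n = 3 chips) than in TN (178 ± 100 CPM, n = 3 chips). Dntt, which encodes the terminal transferase that adds nucleotides at antigen receptor joints, was 5.59-fold higher (log2 fold change 2.48 ± 0.25, SE). Mpo, which encodes the myeloperoxidase of granule-forming myeloid cells, averaged 1824 ± 713 CPM in TN and 41.5 ± 15.4 CPM in Ly6D+ (n = 3 chips each; log2 fold change −5.46 ± 0.44, SE). Of 11797 genes tested with edgeR's quasi-likelihood test on chip sums, 11 were higher and 13 lower in Ly6D+ at an adjusted p under 0.05, and 988 had an unadjusted p under 0.05. The chip values of all 24 called genes did not overlap between populations, against 15.4% of all tested genes and 10% by chance. The calls rest on the same chip values, so this is no separate support for them. The count was 561 with DESeq2 and 326 with limma-trend on chip means, and it was 2 without Ly6D+ chip 6, 4 without Ly6D+ chip 4, 7 without TN chip 3, 8 without TN chip 1 and 12 without TN chip 2.

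**Figure D1:**
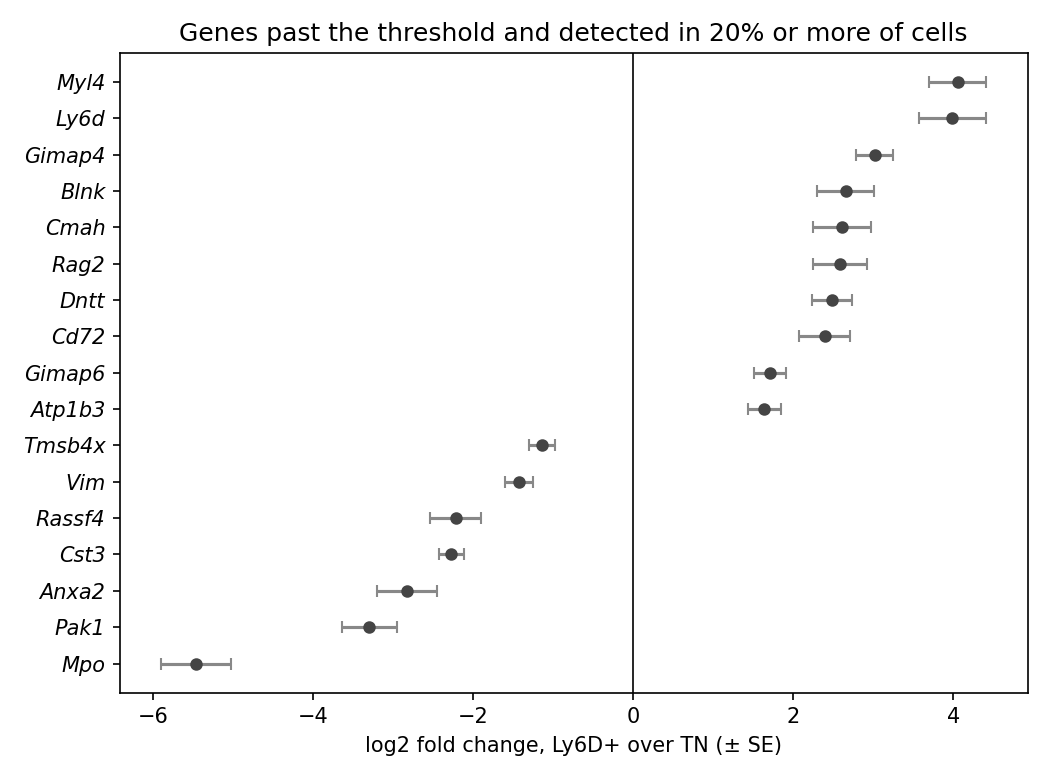
Log2 fold change of Ly6D+ over TN (x axis, points with SE bars, 3 chips against 3) for the 17 genes past the threshold that were detected in 20% or more of the cells of the higher population (y axis). Myl4 lies at 4.05 and Mpo at −5.46.

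Among early lymphoid progenitor genes, 3 of 15 tested members rose in Ly6D+ and 1 fell. Dntt was detected in 93.4% ± 5.9 of Ly6D+ cells and 30.6% ± 5.2 of TN cells (SD, n = 3 chips). Gimap6, a GTPase of the immunity-associated family, rose 3.28-fold and was detected in 93.3% of Ly6D+ and 48.4% of TN cells. Rag2, a subunit of the recombinase that joins antigen receptor segments, rose 6.01-fold (log2 fold change 2.59 ± 0.34, SE). The member that fell was Ikzf3, a lymphoid zinc finger factor, with reads in 5 of 213 TN cells and 0 of 152 Ly6D+ cells, which allows a share of up to 1.97%. Its call on the sums (edgeR adjusted p = 0.0449) rests on these 5 cells, which held a median of 1132 reads. The TN share of 2.35% lies near that limit, so the cell counts hardly show a fall. Adjusted over the list alone, 9 members rose and 1 fell. The list was higher in Ly6D+ by camera (adjusted p = 1.2e-06), with adjusted p = 0.0535 with an estimated correlation.

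B-lineage genes showed 3 of 21 tested members higher in Ly6D+ and none lower (10 higher adjusted over the list alone). Myl4, a myosin light chain, rose 16.6-fold and was detected in 53.2% ± 5.6 of Ly6D+ cells against 10.2% ± 2.7 of TN cells (SD, n = 3 chips). Blnk, the adaptor of B cell receptor signalling, rose 6.30-fold, and Cd72, a B cell surface lectin, 5.26-fold. Camera placed the list higher in Ly6D+ (adjusted p = 1.7e-16), with adjusted p = 0.0535 with an estimated correlation. Each Ly6D+ cell held 6.54 ± 0.40 of the B-lineage members above the detection limit and each TN cell 2.39 ± 0.35 (SD, n = 3 chips, exact two-sided permutation p = 0.1, the smallest this design allows).

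Ebf1, Rag1, Cd79a, Il7r and Pax5 were detected in part of the Ly6D+ cells and did not pass the edgeR test. Ebf1, a factor needed for B-lineage commitment, was detected in 43.4% ± 5.9 of Ly6D+ and 3.75% ± 2.18 of TN cells (SD, n = 3 chips), and its chip sums gave a log2 fold change of 2.89 ± 1.03 (SE, edgeR adjusted p = 0.447). Its CPM on TN chips 1, 2 and 3 was 15.9, 132 and 4.76, and without TN chip 2 the log2 fold change was 5.19 (edgeR adjusted p = 0.0565). One cell of TN chip 2, chosen after its values were seen, held 76.2% of the Ebf1 reads of that chip and also most of its Cd79a (73.8%), Igll1 (92.4%) and Vpreb3 reads (67.1%). Rag1 was detected in 38.01% of Ly6D+ and 1.41% of TN cells (edgeR adjusted p = 0.206), and Cd79a, a chain of the B cell receptor complex, in 36.3% and 1.45% (edgeR adjusted p = 0.610), with 0, 43.6 and 0 CPM on the TN chips. Il7r, the interleukin 7 receptor chain, was detected in 69.6% ± 9.1 of Ly6D+ and 15.5% ± 6.5 of TN cells, with 560 ± 144 and 226 ± 105 CPM (SD, n = 3 chips, edgeR adjusted p = 0.341). Pax5 was detected in 2.78% of Ly6D+ and 0.483% of TN cells, with no call (edgeR adjusted p = 0.987). Ebf1, Rag1 and Il7r passed the threshold with both DESeq2 and limma-trend.

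Myeloid genes lay lower in Ly6D+ as a list, with a minority of members called. Of 20 tested members of the granulocyte and monocyte progenitor list, 2 fell and none rose, and 9 fell adjusted over the list alone. Elane, the neutrophil elastase gene, had reads in 26 of 213 TN cells and in 0 of 152 Ly6D+ cells, which allows a share of up to 1.97%. Mpo was detected in 34.3% ± 3.0 of TN and 12.8% ± 2.6 of Ly6D+ cells (SD, n = 3 chips). Prtn3, another granule protease, was detected in 38.5% of TN and 1.67% of Ly6D+ cells without passing the threshold over all genes (edgeR adjusted p = 0.158). Csf1r, the receptor for the macrophage growth factor, was detected in 30.6% ± 3.8 of TN and 4.98% ± 2.19 of Ly6D+ cells (SD, n = 3 chips), but its CPM on the Ly6D+ chips was 1.65, 134 and 5.96 and the sums gave no call (log2 fold change −1.34 ± 1.26, SE, edgeR adjusted p = 0.852). Without Ly6D+ chip 5 its log2 fold change was −4.97 (edgeR adjusted p = 0.0622). Camera placed the list lower in Ly6D+ (adjusted p = 8.8e-11), with adjusted p = 0.1009 with an estimated correlation.

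Conventional dendritic and MHC class II genes lay lower in Ly6D+ as lists by camera with the preset correlation but not with an estimated one, and 1 of their 20 tested members was called. Cst3, which encodes the protease inhibitor cystatin C, fell in Ly6D+ from 1982 ± 198 to 411 ± 23 CPM (SD, n = 3 chips), and it was the called member among 10 tested conventional dendritic cell genes (2 fell adjusted over the list alone). None of 10 MHC class II genes passed the threshold over all genes, while 6 fell and 1 rose adjusted over the list alone. H2-Eb1 averaged 249 ± 174 CPM in TN and 37.1 ± 19.7 CPM in Ly6D+, and H2-Ob, the member that went up, 92.9 ± 48.5 and 315 ± 108 CPM (SD, n = 3 chips). Camera gave adjusted p = 0.0037 for the conventional dendritic list and 0.00012 for MHC class II, with adjusted p = 0.125 and 0.134 with an estimated correlation. The 14 tested plasmacytoid dendritic genes held no call, with 2 higher and none lower in Ly6D+ adjusted over the list alone, a median log2 fold change of 0.49 and a camera adjusted p of 0.265. Irf8, a factor of dendritic and monocytic lineages, stood at 1216 ± 177 CPM in TN and 783 ± 186 CPM in Ly6D+ (SD, n = 3 chips, edgeR adjusted p = 0.415).

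Further called genes lay outside these lists. Gimap4 rose 8.11-fold in Ly6D+, Cmah, which encodes a sialic acid hydroxylase, 6.11-fold, and Atp1b3, a sodium pump subunit, 3.11-fold. Pak1, a kinase that acts on the cytoskeleton, had a log2 fold change of −3.30 ± 0.35, Anxa2, an annexin, −2.83 ± 0.37, Rassf4, a Ras association domain gene, −2.22 ± 0.32, Vim, which encodes vimentin, −1.42 ± 0.18 and Tmsb4x, which encodes an actin-binding thymosin, −1.14 ± 0.16 (SE). Mst1r, chosen after its values were seen, had reads in 15 of 152 Ly6D+ cells and in 0 of 213 TN cells, which allows a share of up to 1.41%. L1cam, chosen in the same way, had reads in 33 of 213 TN cells and 0 of 152 Ly6D+ cells.

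Genes of the sort followed the gate in part. Of the 6 tested surface genes, Ly6d was called, and it was detected in 94.6% ± 5.5 of Ly6D+ and 15.1% ± 1.5 of TN cells (SD, n = 3 chips); 3 rose adjusted over the list alone. Siglech, a plasmacytoid dendritic lectin gene, was detected in 16.99% ± 3.30 of Ly6D+ and 9.84% ± 1.02 of TN cells, with 144 ± 74 and 45.35 ± 11.04 CPM (SD, n = 3 chips, edgeR adjusted p = 0.266). Itgax, which encodes CD11c, Kit, which encodes the stem cell factor receptor, and Ptprc, which encodes CD45 and its B220 form, had log2 fold changes of −1.12 ± 0.87, −0.57 ± 0.48 and 0.20 ± 0.23 (SE, no call). Flt3, the receptor for the transgenic ligand, stood at 518 ± 86 CPM in Ly6D+ and 311 ± 6 CPM in TN (SD, n = 3 chips, edgeR adjusted p = 0.255). Camera gave adjusted p = 0.016 for the surface list, with adjusted p = 0.151 with an estimated correlation. Because this list names the genes of the sort, its direction is not independent of the gate.

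Interferon-response genes varied between chips of the same population. TN cells held 1.80, 2.01 and 4.16 of the 15 members on chips 1, 2 and 3, and Ly6D+ cells 5.93, 6.28 and 1.77 on chips 4, 5 and 6 (exact two-sided permutation p = 0.4, n = 3 chips each). Usp18, a regulator of interferon signalling, ranged from 113 to 516 CPM on the TN chips and from 142 to 1416 CPM on the Ly6D+ chips. No member was called with edgeR, over all genes or adjusted over the list alone. Camera gave adjusted p = 0.012, with adjusted p = 0.584 with an estimated correlation, which was 0.83 for this list.

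Cell-cycle, metabolic and remaining lists held no called gene over all genes. TN cells held 6.33 ± 0.61 and Ly6D+ cells 5.07 ± 0.23 of 20 G2/M genes (exact permutation p = 0.1), against 10.3 ± 0.5 and 10.5 ± 0.9 of 20 G1/S genes (exact permutation p = 0.8, SD, n = 3 chips each). Glycolysis genes were lower in Ly6D+ by camera (adjusted p = 0.030), with adjusted p = 0.488 with an estimated correlation, and Pgam1 had a log2 fold change of −1.25 ± 0.31 (SE, edgeR adjusted p = 0.220). The glycolysis call was lost without TN chip 3 (adjusted p = 0.179), Ly6D+ chip 5 (0.167) and Ly6D+ chip 6 (0.091). Camera called no difference for G1/S (adjusted p = 0.202), G2/M (0.146), oxidative phosphorylation (0.202), immediate-early and heat-shock (0.860), plasma cell (0.129), T-lineage (0.860), NK and innate lymphoid (0.220), interleukin 7 and STAT5 target (0.362), erythroid (0.376) and stem and multipotent genes (0.924). G2/M genes were called lower in Ly6D+ in 3 of 12 settings, with adjusted p = 4.3e-08 on chip means of log2 CPM, 0.0078 without TN chip 1 and 0.035 without the Xist cells. For the stem and multipotent list the median log2 fold change was 0.35 while camera and the mean pointed down, and for the erythroid list the median was −0.50 while camera pointed up. Fry, which tests whether a list moves on balance, gave adjusted p = 0.0058 for the surface, B-lineage and myeloid lists, 0.011 for conventional dendritic and 0.035 for MHC class II genes. It gave 0.0567 for early lymphoid, 0.0827 for glycolysis and 0.503 for interferon-response genes, which camera called and fry did not.

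Counted per cell, members of 11 of the 23 lists were higher and of 5 lower in Ly6D+ at the smallest p the exact permutation test allows, 0.1 (Benjamini-Hochberg adjusted p = 0.144). Early lymphoid members numbered 8.52 ± 0.54 per Ly6D+ and 4.56 ± 0.36 per TN cell, and myeloid members 2.80 ± 0.22 and 5.55 ± 0.64 (SD, n = 3 chips). Notch target genes numbered 0.960 ± 0.087 and 0.478 ± 0.038, plasma cell genes 1.07 ± 0.03 and 0.411 ± 0.068, T-lineage genes 1.22 ± 0.04 and 0.772 ± 0.130, and NK and innate lymphoid genes 1.89 ± 0.34 and 1.45 ± 0.06. Stem and multipotent genes numbered 3.06 ± 0.33 and 2.51 ± 0.04, and erythroid genes 1.10 ± 0.12 and 0.791 ± 0.146. Interleukin 7 and STAT5 target genes numbered 4.06 ± 0.13 and 3.18 ± 0.05. The T-lineage, the NK and innate lymphoid and the stem and multipotent lists were higher per Ly6D+ cell while camera on the sums pointed lower, without a call. The Notch, plasma cell, T-lineage and NK and innate lymphoid differences rested largely on few members, not on whole lists. Detection rose from 30.03% of TN to 70.8% of Ly6D+ cells for Lck (T-lineage) and from 2.9% to 48.1% for Mzb1 (plasma cell). It rose from 43.42% to 74.98% for Nkg7 (NK and innate lymphoid). In the Notch target list, where 3 of 10 members could be tested, it rose from 39.9% to 67.6% for Notch1 itself and from 5.60% to 24.2% for Hes1. Other members fell, such as Tcf7 (11.13% to 5.06%) and Id2 (44.7% to 38.2%). Mature neutrophil genes numbered 0.028 per TN and 0.012 per Ly6D+ cell (exact permutation p = 0.3), and megakaryocyte, mast cell and basophil genes 0.155 and 0.0526 (exact permutation p = 0.1). Sex-linked genes, which are Xist and 4 Y-linked genes, numbered 1.19 per TN and 1.57 per Ly6D+ cell (exact permutation p = 0.1), beside TN chip 2, where Xist was detected in 41 cells.

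**Figure D2:**
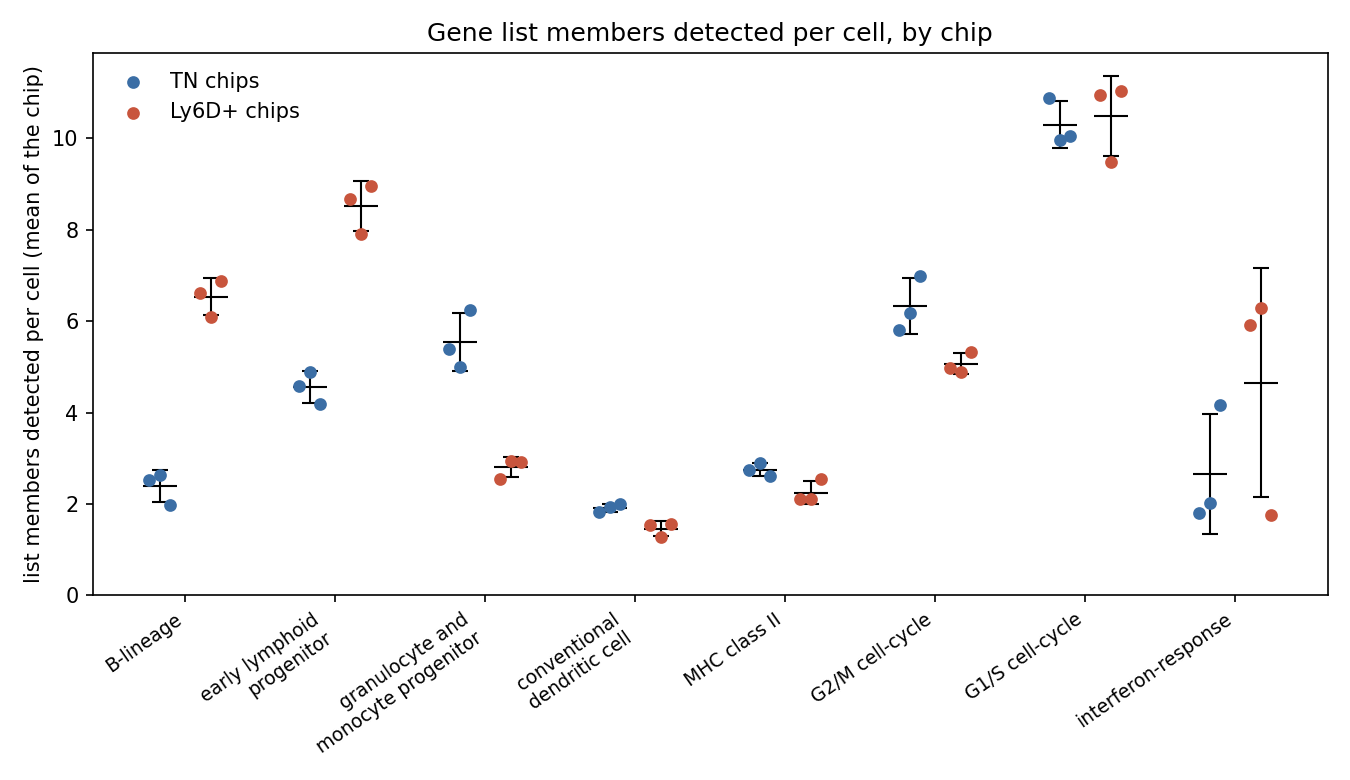
Mean number of list members detected per cell (y axis) for 8 gene lists (x axis), with a point per chip and the mean ± SD of 3 chips in black. B-lineage members lie between 1.99 and 2.64 on the TN chips and between 6.10 and 6.88 on the Ly6D+ chips, while interferon-response members span 1.77 to 6.28 on the Ly6D+ chips.

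Cells of the same chip were compared for their uniformity, with an exact test that cannot go below p = 0.1. TN cells held 2522 ± 84 and Ly6D+ cells 2687 ± 217 detected genes (SD, n = 3 chips, exact two-sided permutation p = 0.4). The mean correlation between cells of a chip was 0.281 ± 0.012 in TN and 0.292 ± 0.019 in Ly6D+ (exact two-sided permutation p = 0.5), and the difference of 0.0104 ranged from 0.00422 to 0.0213 when a chip was left out. Fewer than 1500 genes were detected in 16 TN and 6 Ly6D+ cells, and without these cells edgeR called 24 genes, 13 higher and 11 lower.

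Clustering gave 8 groups of cells, which are described within each population because genes that define them differ between the populations. Among TN cells, cluster 1 was myeloid-like, with Mpo, Prtn3, Ctsg and Csf1r among its top 10 genes, and took 28%, 20.3% and 27.5% of the cells of chips 1, 2 and 3. Cluster 7 was conventional dendritic-like, with H2-Aa, Cd74 and H2-Ab1 in its top 10, and took 12%, 17.4% and 13.04%. Cluster 0, led by Ctsh and the division genes Mki67 and Nusap1, stayed unnamed and took 18.7%, 23.2% and 28.99%. Cluster 2 also stayed unnamed, with 2 T or NK markers (Tcf7, Gata3) among its top 10 genes beside Il7r, and held 28 TN cells. Among Ly6D+ cells, cluster 3 was B-lineage-like, with Blnk, Cd79a and Ebf1 beside Dntt and Il7r in its top 10 together with Gbp7, an interferon-induced GTPase gene, and took 27.5%, 45% and 23.1% of chips 4, 5 and 6. It also held the most interferon-response members per cell, 6.68 against 1.67 to 4.05 in the other clusters. Chip 5, with its largest share, had the most interferon-response (6.28) and fewest B-lineage members (6.10) of the Ly6D+ chips. How far the share follows either list was not tested. Clusters 4, 5 and 6 were lymphoid progenitor-like with Dntt in their top 10, beside replication genes such as Mcm5 in cluster 4 and mitotic genes such as Mki67 in cluster 5, and held 24, 23 and 30 Ly6D+ cells. Cluster 3 also met the rule for lymphoid progenitor-like, with 6 such markers above the other cells, and cluster 6 that for T or NK-like, with 3 such markers and Nkg7 in its top 10. Clusters 3, 4, 5 and 6 also held 7, 14, 16 and 14 TN cells, and clusters 0, 2 and 7 held 8, 15 and 2 Ly6D+ cells. Clusters 2 and 7 had the fewest genes detected, with medians of 1700 and 1633.5 per cell against 2404 to 3265 in the other clusters, and the lowest median depths, about 687460 and 689510 reads. The number of clusters was 4 at resolution 0.5 and 14 at resolution 1.5.

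Within TN cells, myeloid and lymphoid genes were opposed. The Spearman correlation between the myeloid score and the joint early lymphoid and B-lineage score was −0.40, −0.32 and −0.33 on the 3 TN chips (mean −0.35 ± 0.04, SD). On the Ly6D+ chips it was −0.52, −0.29 and −0.06 (mean −0.29 ± 0.23), so its spread there covered most of its size. Given the genes detected per cell, the TN mean was −0.62 ± 0.05 and the Ly6D+ mean −0.20 ± 0.20. The difference between the populations was not tested.

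Genes seen in the same TN cells as Csf1r were Prtn3 (mean rho 0.45 ± 0.12, SD, n = 3 chips), Ly6c2, Gria3, Rrm1, St8sia4, Nup85, Spn, Knstrn, Clec12a and Ms4a6c, and the lowest were Tox (−0.32 ± 0.07), Il2rg, Rgs1, Nr4a1 and H2-Eb1. With Dntt in TN cells went Gimap6 (0.66 ± 0.05), Il12a, Mn1, Lck, Cmah, Gm5111, Nkg7, Emp1, Arpp21 and Ctla2a, and against it Ms4a6c (−0.49 ± 0.18), Ccr2, Tyrobp, Lgals1 and Tmsb4x. With Il7r in TN cells went Ets1 (0.45 ± 0.15), Zfp36l1, Sdc4, Il18r1, Gata3, Cd28, Ppp1r16b, Cmah, Gimap1 and Tcf7, and against it Dek (−0.36 ± 0.13), Anp32b, Kdm1b, Surf4 and Cst3. In Ly6D+ cells Ebf1 went with Cd79a (0.53 ± 0.20), Rag1, Igll1, Vpreb3, Cd79b, Blnk, Cecr2, Mzb1, Gimap4 and B2m, and against Bcl2 (−0.39 ± 0.17), Mtrex, Dync1li1, Irf8 and Fcer1g. Il7r in Ly6D+ cells went with Gm2a (0.37 ± 0.04), Blnk, Rag1, Atp1b3, Cd79a, Mlxip, Vpreb3, Lrmp and Selenop, and against Pgk1 (−0.35 ± 0.08), Cst7, Gm10052, Hnrnpa1l2-ps2 and Gm5643. Dntt in Ly6D+ cells went with Gimap6 (0.45 ± 0.10), Xrcc6, Egfl7, Rps19, Gimap4, Cd84, Tspan32, Dusp2, Cd69 and Akap13, and against the division genes Esco2 (−0.42 ± 0.08), Pclaf, Tacc3 and Racgap1 and the protease gene Ctsh. Of 6805 genes compared with each anchor in TN cells, 99% had a mean rho under 0.32 with Dntt, 0.30 with Csf1r and 0.19 with Il7r. Il7r was detected in 12, 15 and 6 cells of TN chips 1, 2 and 3. The genes listed were chosen for the same sign on all 3 chips. Genes are not independent replicates, and Ebf1 in TN cells and Csf1r in Ly6D+ cells were too rare for this comparison.

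The most variable genes among TN cells, with chip as a block, included lineage genes. They were Id2, detected in 44.7% ± 5.2 of cells (SD, n = 3 chips), Cd69, Mpo, Cd93, Top2a, Dntt, Spcs3, Btg2, H2-Aa and Cnot9. Among Ly6D+ cells they were Top2a, a replication enzyme detected in 59.2% ± 6.6 of cells, Spcs3, Septin11, Mier3, Inafm2, Poldip3, Usp22, Egr1, Milr1 and Irf8. These genes are ranked without a p-value.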

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

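The tests without low-complexity cells, without Xist cells and without TN cells that hold Ly6d were chosen after the data were seen; the others were planned. The 24 called genes became 561 with DESeq2 and 326 with limma-trend on chip means, 7 without Xist cells, and 2 (without Ly6D+ chip 6) to 23 (without Ly6D+ chip 5) when a chip was left out; the cause was not tested for the first 2, and fewer samples or cells enter the others. Higher genes made up 45.8% of calls, against 43.5% with library size alone, 47.6% with DESeq2, 67.8% with limma-trend, and 30.4% (without Ly6D+ chip 5) to 62.5% (without TN chip 1) when a chip was left out. The remaining settings gave 23 to 35 calls. Of the 24 genes, 24 were shared with DESeq2 and 23 with limma-trend in the same direction, and 2 to 13 when a chip was left out. The 8 gene lists called by camera became 0 with an estimated correlation and 5 to 8 when a chip was left out, with 5 without Ly6D+ chip 5. The smallest camera adjusted p with an estimated correlation was 0.0535. For the surface (−0.060), early lymphoid (−0.019) and conventional dendritic lists (−0.014) the estimate lay below the preset 0.01. A higher correlation therefore does not account for those losses, and the estimated setting changes more than the correlation. How far correlation accounts for the losses of the other lists was not tested. Interferon-response genes lost their call without TN chip 1 or 2 and without Ly6D+ chip 4 or 5 (adjusted p 0.0806 to 0.431), glycolysis genes without TN chip 3 and Ly6D+ chip 5 or 6 (0.0912 to 0.179), and the surface list without Ly6D+ chip 5 (0.0755). G2/M genes gained a call in 3 of 12 settings, and plasmacytoid dendritic (0.0478, without Ly6D+ chip 6) and plasma cell genes (0.0344, without TN chip 2) in 1 each.

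The 18 called genes of the naming rule kept their direction in all 288 refits and lost the threshold in 90 of them. For the 12 genes of the rule that were not called, 15 of 188 refits passed the threshold and 5 turned the direction, Ptprc to −0.011 without Ly6D+ chip 5 (up to 0.309 when another chip was left out) and Pax5 to −0.17 without TN chip 1, −0.18 without TN chip 3, −0.18 without Ly6D+ chip 5 and −1.05 without Xist cells, with 9.65 the highest when a chip was left out.

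Differences per cell kept their direction in 263 of 276 refits of lists. The 13 that turned belong to lists with differences near 0: G1/S genes (0.188 to −0.0417 without Ly6D+ chip 4, −0.0859 without chip 6, −0.113 at 20 reads, −0.142 without low-complexity cells), immediate-early genes (0.0703 to −0.0293 without TN chip 1, −0.115 without Ly6D+ chip 6, −0.0437 at 20 reads, −0.0400 without Xist cells) and oxidative phosphorylation genes (−0.0402 to 0.202 without TN chip 1, 0.484 without Ly6D+ chip 5, 0.103 at 1 read, 0.0490 without thinning, 0.130 without TN cells with Ly6d). When a chip was left out, these 3 ranged from −0.0859 to 0.692, −0.115 to 0.236 and −0.310 to 0.484. The exact test cannot pass 0.05 here, so these refits say nothing of significance. The TN relation of myeloid and lymphoid genes moved from −0.35 to −0.42 with a pseudocount of 10, −0.28 with members detected, −0.62 given the genes per cell and −0.48 without low-complexity cells, and the cause was not tested. Clusters numbered 8, 4 at resolution 0.5 and 14 at resolution 1.5. At this depth and spread the simulated tests recovered 5% of 2-fold changes, so a gene without a call is not shown to be unchanged.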

Other observations

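The tests on Il7r-positive cells were chosen after the correlations of Il7r were seen, those on a few responding cells, on the mix of TN cells, on the share of each cluster and on mice, day or handling after the interferon values, those on carried reads and on mixed sexes after the Xist values, and the other splits of the chips after the called genes. The tests on Ly6d, on genes detected per cell, on the mix of Ly6D+ cells by Ebf1, on the ratio of fold changes and on splits for gene lists were fixed before their values were known, except that the bootstrap spreads and the comparison at equal numbers of detected genes were added afterwards. A gene counts as detected in a cell at 5 or more thinned reads, and cells with a gene, or without it, are those above or below this limit unless any read is named.

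Xist, which is transcribed from the inactive X chromosome of female cells and was not among the genes tested with edgeR, was detected in 41 of the 69 cells of TN chip 2 and in no cell of the 5 other chips (at any read, in 43 cells and in 1 cell each of chips 3 and 5). Reads carried between wells do not account for it, since 0 of the 17 cells of that chip with a Y-linked gene detected also held Xist, against 41 of the other 52, and at any read 2 of 21 did, against 41 of 48. The 17 cells with a Y-linked gene and no Xist beside 41 with Xist are consistent with a pool of a female and a male mouse. The Xist cells are an unlikely sole source of the called genes, since TN chips 1 and 3, where Xist was not detected, also lay apart from the Ly6D+ chips for all 24. The genes were called from these same chip values, which favours such a separation, so it is no separate test. The median ratio of the log2 fold changes of the called genes without and with the Xist cells was 0.9998 over the 23 genes that could be tested again, all 23 with the same sign. Because the Xist cells lay on 1 of the 3 TN chips, this ratio could hardly have fallen far and adds little. The number of calls went from 24 to 7 without those 41 cells, and leaving out 41 cells of the chip at random gave 5 to 25 calls (median 10.5, 20 draws), so the loss of cells alone reaches such counts.

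Ly6d was detected in 10, 11 and 11 cells of the TN chips, which were sorted without the protein. These cells held 3.48 ± 1.40 more early lymphoid and B-lineage members than the other TN cells of their chip (SD, n = 3 chips), and 2.83 ± 1.40 more at equal numbers of detected genes. On chips 1, 2 and 3 the latter was 1.60 ± 0.68, 4.36 ± 1.55 and 2.54 ± 0.80 (bootstrap SD), above 0 on each chip, which argues against reads carried at random between wells as the whole source, though chip 1 fell short of the 2 members set in advance, which all 3 chips reached without this adjustment. The TN cells with Ly6d held 3.43 ± 1.20 B-lineage members against 6.48 ± 0.29 in Ly6D+ cells with Ly6d, and a median Ly6d level of 353 against 2060 CPM (means of 3 chips). This argues against typical Ly6D+ cells in the TN gate as the whole source. Because the comparison was with whole Ly6D+ chips, it cannot exclude Ly6D+ cells low in Ly6D, which were not compared apart. No biological explanation was tested.

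The interferon pattern was seen in most cells of some chips. On chips 1 to 6, 26.7%, 36.2%, 62.3%, 92.5%, 75% and 25% of cells held 3 or more of the 15 members, and the highest, 92.5%, argues against a few strongly responding cells. The number of genes detected per cell does not account for it, since among cells with 2000 to 3000 genes the range of the chip means was 1.14 ± 0.11 times that over all cells (bootstrap SD). With each cluster of 2 or more cells per chip at the same weight on each chip, the range was 0.931 ± 0.058 times that over all Ly6D+ cells (4 clusters, 127 cells) and 0.918 to 1.33 times at 5 such minimums, from 1 to 7 cells. It was at least 1.01 ± 0.10 times among Ly6D+ cells with and without Ebf1, which together argue against the mix of cells as the whole source on the Ly6D+ chips, though within cluster 6 it was 0.579 ± 0.153 times (13, 4 and 13 cells). On the TN chips the part of the mix stays open, since the same weighting gave 0.854 ± 0.050 (6 clusters, 192 cells) but 0.771 to 0.902 over the 5 minimums, and the range was 1.36 ± 0.29 times within cluster 1 and 0.254 ± 0.375 times within cluster 6 (5, 7 and 2 cells). On TN chip 2 the cells with Xist held 1.93 fewer members than those with a Y-linked gene (1.54 against 3.47, a difference of −1.93), with 2569 and 2813 genes detected, and cells of 1 chip do not measure a difference between mice. Mice, day and handling of a chip cannot be told apart, because each chip holds 1 population and the labels do not tie mice to chips. Each chip also has its own code in the cell titles, which reads like a date but is not named as one. The range between chips was 2.36 members in TN and 4.51 in Ly6D+.

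Il7r was detected in TN cells with and without Dntt. Of 33 TN cells with Il7r above the detection limit, 14 had Dntt below it, and 11 of these held Gata3, Tcf7, Tox or Zbtb16, genes of innate and T lymphoid development, against 7 of the 19 with Dntt, a difference of 42.6 ± 12.8 percentage points (SD, n = 3 chips). Gata3 and Tcf7 were picked from the genes that went with Il7r in the same cells, so these counts do not test whether there are 2 kinds of cell. The cells without Dntt numbered 6, 6 and 2 per chip and had fewer genes detected on each chip (1512 against 3067, 2222 against 2461 and 2032 against 2362).

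The 24 called genes cannot be set against chance by regrouping, because the 6 chips make 10 splits. The real split gave 24 genes and the highest of the others 0, and 1 of the 10 splits gave as many. For gene lists tested with camera the real split gave 8 lists and the highest of the others 4, again with 1 of 10 splits giving as many.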
